A study of Mus musculus with 15 samples.

How the data were processed

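Gene expression was measured by RNA sequencing in 15 libraries of total RNA from the tibialis anterior, a muscle of the lower hind leg, of male C57BL/6 mice. Per the labels, the libraries were made with the MGIEasy RNA Directional kit, reads were trimmed with Trim Galore, aligned with STAR 2.7.9a and counted with RSEM 1.3.3. The genome build and annotation were not given in the sources used here, and the labels do not say whether the strand of the reads was used in counting, so values of antisense genes such as Irx3os and Foxo6os, and of genes with close copies such as Acot1 and Acot2, Mt1 and Mt2, Hba-a1 and Hbb-bs, are less certain. The deposited values of each library are RSEM expected counts for 55416 genes, of which 52083 carried a symbol and 3333 did not. Genes without a symbol held at most 0.386% of a library. Between 19.8% and 22.8% of the non-zero values of a library were not whole numbers, since RSEM divides reads between genes.

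The expected counts were rounded to whole numbers. Library totals were 15894822 to 22459370. A count of 0 allows a level of up to 0.134 to 0.189 CPM (counts scaled to a common library size), the level that 3 counts would give in the deepest and the shallowest library. Such floors, and the 95% intervals of ratios of low counts, cover counting error only.

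Groups were taken from the labels: control without tumour (n = 5), and tumour-bearing mice given isotype IgG (n = 4), anti-PD-L1 (n = 3) or anti-CD8a (n = 3). All 6 pairs of groups were compared. The labels do not say that each library came from a different mouse, so the p-values of single genes measure the spread between these libraries. No litter, cage, day or sequencing batch was given. Replicate numbers did not pair the libraries: in 2 of 19 pairings a library correlated best with the library of the same number, so the comparisons were unpaired.

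The 4 groups were fitted together in edgeR 4.0.16 (R 4.3.3) with TMM normalization, filterByExpr with the groups, a quasi-likelihood fit and test (11 residual degrees of freedom), and Benjamini-Hochberg adjustment within each comparison. The filter left 14372 genes, and a gene was called changed at an adjusted p under 0.05. Log2 fold changes are given with a standard error, computed as the absolute log2 fold change divided by the square root of the test's F. Levels are TMM-normalised CPM, as mean ± SD over the libraries of a group. Log2 CPM used a prior count of 2.

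Gene groups were 26 lists: atrophy genes, proteasome subunits, cathepsins with lysosome and autophagy, T and cytotoxic lymphocytes, B and plasma cells, macrophages and antigen presentation, neutrophils, interferon response, acute phase and cytokine response, fast and slow contractile genes, denervation and neuromuscular junction, muscle satellite cells and regeneration, extracellular matrix and fibroblasts, tenocytes, oxidative phosphorylation, glycolysis and glycogen, fatty acid use and PPAR targets, integrated stress response, immediate early and heat shock genes, circadian clock, adipocytes, endothelial cells, Schwann cells, red blood cells and epithelial cells. No gene stood in more than 1 list. Each list was tested with camera (limma 3.58.1, on voom values, preset correlation 0.01, adjusted over the lists of a comparison), and its members were counted over all genes tested and adjusted over the list alone. Camera sets the members of a list against the other genes, so its p-values do not measure the spread between libraries alone. Members below the filter were not tested: 18 of 22 in the T cell list, 8 of 10 in the B cell list, 7 of 13 in the neutrophil list, 7 of 11 in the epithelial list, 4 in the stress response list and 0 to 2 in each other list.

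Genes were named by a rule. Ctsl, Trim63, Fbxo32, Cd8a and Cd274 were named in every comparison. In IgG against control, anti-PD-L1 against IgG and anti-CD8a against IgG, the 10 higher and 10 lower genes of largest log2 fold change were named, and 5 of each in the other comparisons. They had to be called, to have a mean CPM of at least 1 and ranges of the compared groups that did not overlap, and to carry a symbol not of the Gm or Rik type. For each list, up to 4 called members of largest change were named, or the member of smallest p as a value where none was called. The groups, comparisons, model, lists and naming rule were fixed before the data were examined. Spon2 was named outside the rule, after its values were seen.

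Fold changes of comparisons that share a group were correlated across genes and set beside 20 simulations of unchanged groups against the same shared libraries, the overlap expected of independent lists, and runs in which the shared libraries were divided between the comparisons. The share of counts from mitochondrial genes, with 3 mitochondrial pseudogenes, was compared by a two-sided exact permutation test, adjusted over the 6 comparisons.

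The model was tested on simulated data with 200 genes changed in each comparison's design: 40% to 56% of genes changed 2-fold and 82% to 91% of those changed 4-fold were recovered, with 4.43% to 8.18% of calls false. A simulated shift of 1 list was found each time, and at most 1 of the 26 lists was called without a shift. The simulated genes varied independently, and far fewer changed than in most comparisons, so these rates need not hold for the real data. They do not test the preset correlation used for the lists.

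Alternatives tried were RLE and upper-quartile normalization, no filter on low counts, a mean CPM of at least 1, mitochondrial genes left out, replicate number as a block, at least a 2-fold change, voom with sample quality weights, a fit of only the 2 groups compared, DESeq2 1.42.0, each replicate left out in turn, camera with an estimated correlation, fry, and the shared libraries divided. Leaving out IgG replicate 2 and anti-PD-L1 replicate 2 together was added after the data were seen. Other splits of the libraries of each comparison were counted, at most 100 for each. The TPM and FPKM values in the same files were left out, since the tests need counts.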

Results

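RNA was sequenced from the tibialis anterior muscle of male C57BL/6 mice that were 6 to 8 weeks old. In 3 of the 4 groups, cells of the tumour line KrasIKKaL had been placed in the airway. These tumour-bearing mice received, by injection into the abdomen, an isotype IgG (n = 4), an antibody against the checkpoint ligand PD-L1 (200 µg per kg, n = 3) or an antibody against CD8a, the coreceptor of cytotoxic T cells (200 µg, n = 3). The 2 therapeutic antibodies were given 3 times a week, and control mice had no tumour (n = 5). Library totals were 17664347 to 19786207 expected counts in control, 15894822 to 18768544 in IgG, 17825801 to 22459370 in anti-PD-L1 and 18525224 to 20019364 in anti-CD8a. Between 18571 and 19970 genes had a count above 0 in a library. The series states its purpose as finding targets for cachexia, the wasting of muscle in cancer, and for adverse immune effects of therapy on muscle, and its title names Cathepsin L.

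The first principal component held 56.1% of the variance of log2 CPM and set the IgG libraries, at 38.0 to 92.3, apart from control, at -59.5 to -43.6. The anti-CD8a libraries lay at -41.3 to -33.8, and the anti-PD-L1 libraries at 4.98 to 60.5. IgG replicate 2, at 38.0, lay lowest of its group, and anti-PD-L1 replicate 2, at 60.5, highest of its group. Mitochondrial transcripts made up 27.0% ± 3.17 (SD, n = 5) of counts in control, 19.6% ± 2.32 (SD, n = 4) in IgG, 17.3% ± 1.85 (SD, n = 3) in anti-PD-L1 and 27.2% ± 1.71 (SD, n = 3) in anti-CD8a.

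**Figure D1:**
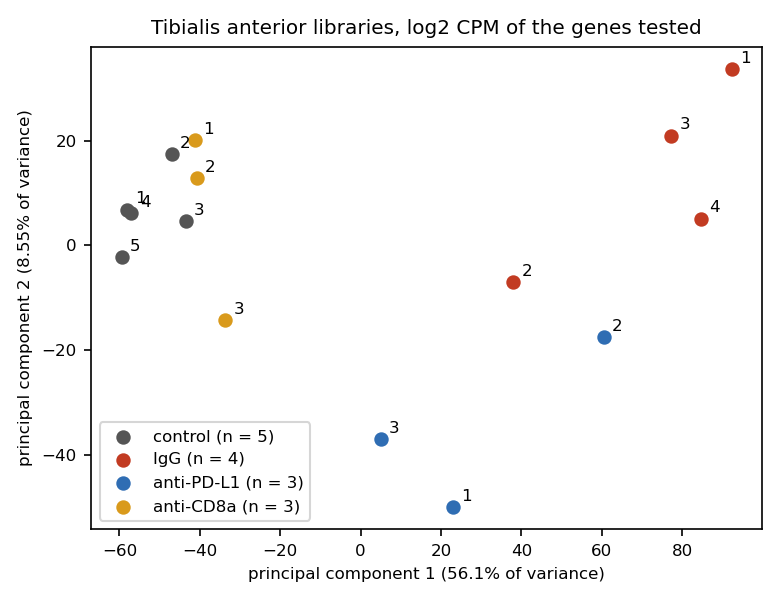
Each point is 1 library, placed by its scores on the first (56.1% of variance) and second (8.55%) principal components of log2 CPM, with colour for the group. IgG libraries lie at 38.0 to 92.3 on the first component, control libraries at -59.5 to -43.6 and anti-CD8a libraries at -41.3 to -33.8.

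IgG against control set tumour-bearing mice given isotype IgG against mice without tumour. The labels name no antibody for control mice, so in each comparison with control the tumour and the injected antibody changed together and cannot be separated. Genes of muscle protein breakdown rose together. Ctsl (ENSMUSG00000021477), the lysosomal protease Cathepsin L named in the title, rose from 80.2 ± 6.59 CPM (SD, n = 5) to 381 ± 111 CPM (SD, n = 4), a log2 fold change of 2.25 ± 0.24 (SE, adjusted p = 2.25e-06). The muscle ubiquitin ligases rose more: Trim63 (ENSMUSG00000028834) from 521 ± 422 to 4790 ± 812 CPM, by 3.20 ± 0.45 (SE) in log2, and Fbxo32 (ENSMUSG00000022358) from 465 ± 113 to 4057 ± 646 CPM, by 3.12 ± 0.25. Collagen genes fell, with Col3a1 down from 197 ± 36.1 to 6.00 ± 3.40 CPM. In all, 8410 of 14372 genes changed, 4335 higher and 4075 lower, of which 4292 passed and changed at least 2-fold.

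Of the 20 atrophy genes, a list of muscle ubiquitin ligases and targets of FoxO and glucocorticoid signalling, 19 rose and 1 did not pass (19 adjusted over the list alone). Camera gave an adjusted p of 4.35e-08, against adjusted p = 0.387 with an estimated correlation. Cdkn1a, an inhibitor of the cell cycle, rose from 27.4 ± 20.4 to 507 ± 225 CPM, and Eif4ebp1, a brake on protein synthesis, from 48.2 ± 10.0 to 479 ± 142 CPM. All 31 proteasome subunits rose, among them Psmd4 by 2.26 ± 0.20 (SE) and Psmd11 by 2.19 ± 0.17 in log2 (camera adjusted p = 3.48e-15, adjusted p = 0.387 with an estimated correlation). In the list of cathepsins, lysosome and autophagy, 17 of 26 rose and 2 fell (camera adjusted p = 3.68e-05, adjusted p = 0.387 with an estimated correlation). Bnip3, a receptor for the removal of mitochondria, rose from 248 ± 32.8 to 1549 ± 535 CPM and Sqstm1, an autophagy cargo receptor, from 493 ± 32.9 to 1967 ± 369 CPM.

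**Figure D2:**
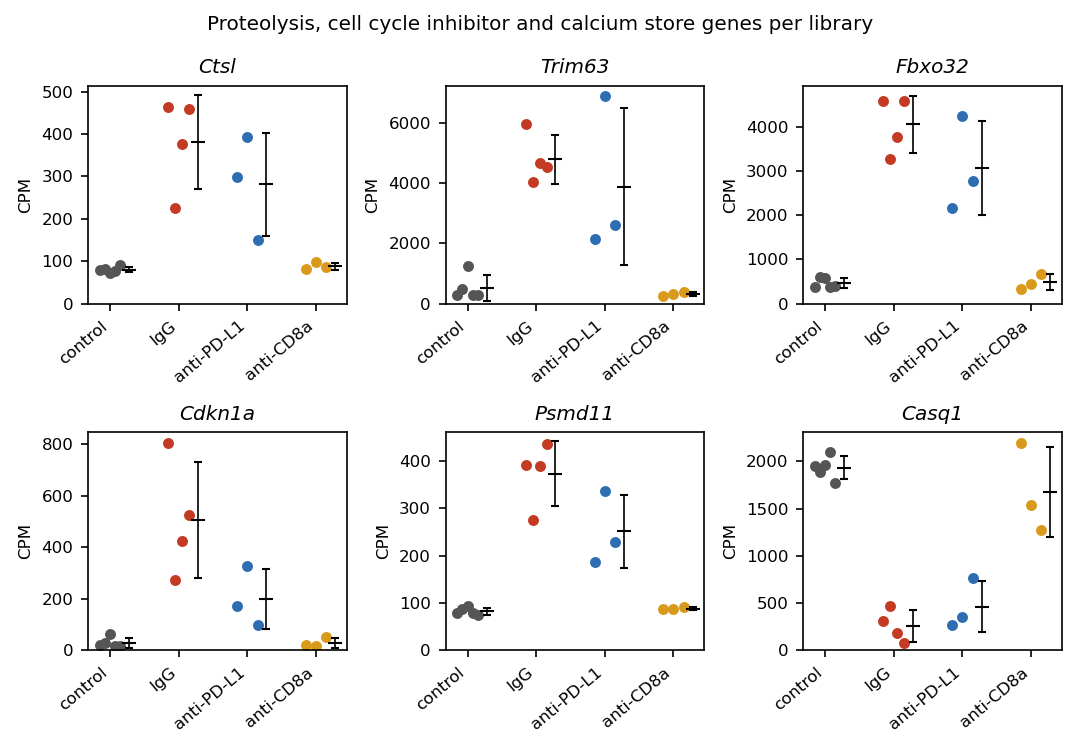
Levels of Ctsl, Trim63, Fbxo32, Cdkn1a, Psmd11 and Casq1 in CPM on linear axes from 0, with a point for each library and a bar for the mean ± SD of each group. Ctsl averaged 80.2 CPM in control, 381 in IgG, 281 in anti-PD-L1 and 88.1 in anti-CD8a.

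Genes of oxidative phosphorylation and glycolysis were lower in IgG than in control. Of 46 measured genes of oxidative phosphorylation, 37 fell and 1 rose (40 and 1 adjusted over the list alone), with Cox7a1 down by a log2 change of -1.63 ± 0.18 (SE) and Cyc1 by -1.28 ± 0.14. Camera gave this list an adjusted p of 2.89e-09, and adjusted p = 0.476 with an estimated correlation. The mitochondrial share of counts differed by -7.37 percentage points (exact permutation p = 0.0159, two-sided; 0.0537 adjusted over the 6 comparisons). In glycolysis and glycogen use 11 of 18 fell and 2 rose (camera adjusted p = 0.00644, adjusted p = 0.493 with an estimated correlation), with Pgam2 down from 1419 ± 192 to 260 ± 96.6 CPM and Eno3 from 3617 ± 489 to 965 ± 527 CPM. Among fast contractile genes 8 of 16 fell and 1 rose (camera adjusted p = 0.113), with the calcium store protein Casq1 down from 1935 ± 119 to 259 ± 169 CPM. Of 12 slow contractile genes 3 rose (1 adjusted over the list alone; camera adjusted p = 0.0739), and 1 did so with upper-quartile normalization, without control replicate 4 or without IgG replicate 4. The count was 9, 5 and 6 without control replicate 2, IgG replicate 1 and IgG replicate 2.

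Connective tissue and nerve support genes fell in IgG. In the extracellular matrix and fibroblast list 21 of 24 fell and 1 rose (camera adjusted p = 1.46e-08, adjusted p = 0.387 with an estimated correlation), with Col1a1 at 3.44 ± 1.89 against 101 ± 26.6 CPM and Col1a2 at 12.5 ± 4.68 against 176 ± 34.4 CPM. Tendon cell genes fell in 6 of 8 cases (camera adjusted p = 0.0221, adjusted p = 0.491 with an estimated correlation), such as Tnmd by -3.80 ± 0.51 (SE) in log2. Of 9 Schwann cell genes, which mark the sheath of nerves, 7 fell (camera adjusted p = 0.0288, adjusted p = 0.647 with an estimated correlation), with S100b at -2.80 ± 0.49, and 4 fell without control replicate 3 or 5 or without IgG replicate 3 or 4. The camera call of this list was lost without control replicate 3 or IgG replicate 3 or 4, at adjusted p values of 0.0514, 0.0511 and 0.0688. Of 12 endothelial genes 3 fell and 1 rose (0 and 1 adjusted over the list alone; camera adjusted p = 0.345). In edgeR, 5 endothelial genes fell with upper-quartile normalization, 1 fell without control replicate 2, and 0 fell without control replicate 5 or IgG replicate 1.

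Resident immune genes and interferon targets were lower in IgG while inflammatory response genes were higher. The macrophage and antigen presentation list had 16 of 23 lower and 1 higher (camera adjusted p = 0.00459, adjusted p = 0.642 with an estimated correlation). Folr2, a marker of resident macrophages, fell from 3.98 ± 1.52 to 0.259 ± 0.231 CPM, while Cd68, a lysosomal protein of macrophages, rose from 2.81 ± 0.583 to 21.3 ± 15.1 CPM. In the IgG libraries other than replicate 2, Folr2 lay at 0.122 to 0.189 CPM, about the floor, so the size of its fall is uncertain. Of 35 interferon response genes 24 fell and 2 rose (camera adjusted p = 3.16e-06, adjusted p = 0.387 with an estimated correlation), with the T cell attractants Cxcl9 down by -3.30 ± 0.58 (SE) and Cxcl10 up by 2.78 ± 0.63 in log2. Cd274 (ENSMUSG00000016496), the gene of PD-L1, did not pass, at 1.68 ± 0.577 against 3.22 ± 2.02 CPM (-0.95 ± 0.43, adjusted p = 0.0668). In the acute phase and cytokine list 13 of 18 rose (14 adjusted over the list alone; camera adjusted p = 0.00644, adjusted p = 0.476 with an estimated correlation), with Lcn2, which binds bacterial iron carriers, up from 1.64 ± 1.53 to 29.7 ± 20 CPM and Il6ra from 10.5 ± 5.65 to 147 ± 44.1 CPM. Neutrophil genes rose in 4 of 6 cases and fell in 1 (camera adjusted p = 0.26), and 2 rose without IgG replicate 2. S100a8 rose from 0.454 ± 0.681 to 2.59 ± 1.19 CPM.

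Few T and B cell genes could be tested. Cd8a had 0 to 4 counts in each library and was below the filter. Of 4 tested T cell genes 1 fell, Cd3e, at a raw count ratio 19.7-fold lower in IgG (95% counting interval 6.50 to 97.4), and camera gave the list an adjusted p of 0.26. Of 2 tested B cell genes 1 fell, Ighm, from 48.0 ± 5.45 to 6.72 ± 9.97 CPM (camera adjusted p = 0.385).

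The largest rises in IgG, beyond Cdkn1a, were in Ffar4, Ripor3, Cdhr3, Acot1, Tecrl, Chil3, Gnmt, Doc2b and Wdr62, with log2 fold changes of 4.20 to 7.02. Ffar4, a receptor for long-chain fatty acids, was 162-fold higher in raw counts (95% counting interval 44.3 to 1350). The largest falls, beyond Col3a1, were in Irx3os, Apln, Nrep, Kcng4, Lrrc38, Pde4a, Rmi2, Kera and Plcd4. Nrep fell from 162 ± 17.8 to 2.61 ± 1.99 CPM, and Irx3os had 0 counts in every IgG library, at least 56.1-fold lower against a floor of 3 counts over the group. Of the 109 named genes that passed, 17 lost the call under at least 1 alternative, S100a9 without IgG replicate 2 among them. Without IgG replicate 2 and anti-PD-L1 replicate 2, 8908 genes changed.

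Anti-PD-L1 was compared with IgG to see what blocking the checkpoint did to muscle in tumour-bearing mice. Macrophage genes rose: Adgre1, the F4/80 antigen, stood at 6.54 ± 4.83 CPM (SD, n = 3) against 0.797 ± 0.270 (SD, n = 4), a log2 fold change of 3.02 ± 0.49 (SE, adjusted p = 0.00512). Folr2 rose by 3.80 ± 0.60 and Pf4 by 2.89 ± 0.44. The calls of Adgre1 and Folr2 were each lost under at least 1 alternative, that of Pf4 under none. Apart from replicate 2, the IgG libraries held Folr2 at 0.122 to 0.189 CPM, about the floor of 0.134 to 0.189 CPM. The size of its rise is therefore uncertain. With all libraries the atrophy genes did not pass in either direction, and 3 of 20 were lower without anti-PD-L1 replicate 2. Ctsl stood at 281 ± 122 against 381 ± 111 CPM (-0.44 ± 0.27, adjusted p = 0.297), Fbxo32 at 3063 ± 1061 against 4057 ± 646 CPM (-0.41 ± 0.28, adjusted p = 0.353) and Trim63 at 3878 ± 2606 against 4790 ± 812 CPM (-0.30 ± 0.49, adjusted p = 0.723). In all, 791 genes changed, 569 higher and 222 lower.

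Of 23 measured macrophage and antigen presentation genes, 21 were higher in anti-PD-L1 than in IgG (22 adjusted over the list alone; median log2 fold change 2.27, camera adjusted p = 4.2e-19, adjusted p = 0.314 with an estimated correlation), and 13 were without IgG replicate 4. Lysozyme Lyz2 rose from 30.1 ± 11.2 to 211 ± 156 CPM, a call lost without anti-PD-L1 replicate 1. The largest rises included the membrane receptor genes Ms4a4a at 3.02 ± 0.47 (SE) and Ms4a6c at 3.08 ± 0.53 in log2, and C3 of the complement system rose from 30.8 ± 14.8 to 114 ± 38.0 CPM as the 1 of 18 acute phase genes to pass (2 adjusted over the list alone, camera adjusted p = 0.646). In the matrix and fibroblast list 12 of 24 rose (16 adjusted over the list alone; camera adjusted p = 1.53e-07, adjusted p = 0.565 with an estimated correlation), among them Pi16, a marker of fibroblasts around vessels, by 3.26 ± 0.50 and Fn1, fibronectin, from 21.1 ± 12.3 to 83.3 ± 32.7 CPM. Only 2 matrix genes rose without anti-PD-L1 replicate 3, 5 without IgG replicate 1 or 4, and 7 without IgG replicate 3 or anti-PD-L1 replicate 1. Neutrophil genes rose in 3 of 6 cases (4 adjusted over the list alone; camera adjusted p = 0.00368, adjusted p = 0.53 with an estimated correlation), with S100a8 at 16.6 ± 10.7 against 2.59 ± 1.19 CPM. None of these 3 passed in edgeR without IgG replicate 1, 3 or 4 or without anti-PD-L1 replicate 1.

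Proteasome subunits had lower values as a list (median log2 fold change -0.36, camera adjusted p = 2.05e-07, adjusted p = 0.732 with an estimated correlation), yet 0 of 31 passed, with Psmc4 at -0.76 ± 0.22 (SE, adjusted p = 0.0532). The same held for slow contractile genes (0 of 12 passed, median -1.31, camera adjusted p = 0.00687), red blood cell genes (0 of 6, median -1.58, 0.00571) and fatty acid genes (0 of 24, median -0.34, 0.0477), each with adjusted p = 0.732 with an estimated correlation. The members of smallest p were Alas2 at -1.83 ± 0.72 (adjusted p = 0.12) and Acot1 at -1.91 ± 0.75 (adjusted p = 0.122). For oxidative phosphorylation 0 of 46 passed and the median was 0.12 (camera adjusted p = 0.0477, adjusted p = 0.809 with an estimated correlation). Of the 20 atrophy genes 0 passed (camera adjusted p = 0.0607, and 0.0059 to 0.732 over the alternatives). In the lysosome list Ctsh alone rose, from 5.14 ± 1.08 to 11.6 ± 3.88 CPM (camera adjusted p = 0.115), a call lost without anti-PD-L1 replicate 1. No interferon response gene passed over all genes, though 5 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0638). Endothelial genes had 0 of 12 past the threshold and a median of -0.15 (camera adjusted p = 0.275). Tendon cell, glycolysis, fast contractile and Schwann cell genes had 0 members past the threshold and camera adjusted p values of 0.753, 0.373, 0.993 and 0.74. Of 4 T cell genes Cd2 rose, by 3.06 ± 0.76, a call lost without IgG replicate 1, 3 or 4 or anti-PD-L1 replicate 1 or 3 (camera adjusted p = 0.45). Neither B cell gene passed, with Igkc at 10.3 ± 17.0 against 1.27 ± 2.21 CPM (camera adjusted p = 0.373). Cd274 stood at 0.982 ± 0.430 against 1.68 ± 0.577 CPM (-0.78 ± 0.51, adjusted p = 0.334). Calls in these lists rose when 1 library was left out. Without anti-PD-L1 replicate 2, 9 proteasome, 3 atrophy, 8 lysosome, 5 red blood cell and 1 interferon genes were lower, and 3 lysosome, 7 interferon and 3 oxidative phosphorylation genes were higher. Without IgG replicate 2, 16 proteasome, 6 lysosome, 3 fatty acid, 2 glycolysis and 1 interferon genes were lower, and 2 lysosome, 4 interferon, 3 glycolysis and 2 B cell genes were higher. With upper-quartile normalization 2 interferon genes were higher. Camera calls also hung on single libraries. Over the runs with 1 library left out, red blood cell and slow contractile genes passed in 5 of 7 (up to 0.0958 and 0.167). Fatty acid and oxidative phosphorylation genes passed in 3 of 7 (up to 0.407 and 0.142). Without anti-PD-L1 replicate 1 camera also called glycolysis (0.0103) and fast contractile genes (0.0431). Without IgG replicate 1 it called endothelial (0.00998) and interferon genes (0.0183), and without IgG replicate 2 lysosome genes (0.0128). Among genes that fell, Acaca, which makes malonyl-CoA for fatty acid synthesis, went from 48.0 ± 18.7 to 18.4 ± 4.06 CPM, a call lost without anti-PD-L1 replicate 3.

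This comparison depended on single libraries: 147 genes changed without anti-PD-L1 replicate 1, 158 without replicate 3, 2712 without replicate 2, 162, 313 and 210 without IgG replicate 1, 3 and 4, 2604 without IgG replicate 2, and 4215 without both replicates 2. A fit of these 2 groups alone called 37 genes, all higher, and DESeq2 called 1756, with 863 higher and 893 lower. Of the 35 splits of the libraries, 3, the real one included, called as many as 791. Of the 34 named genes that passed, 33 lost the call under at least 1 alternative, and Pf4 did not.

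**Figure D3:**
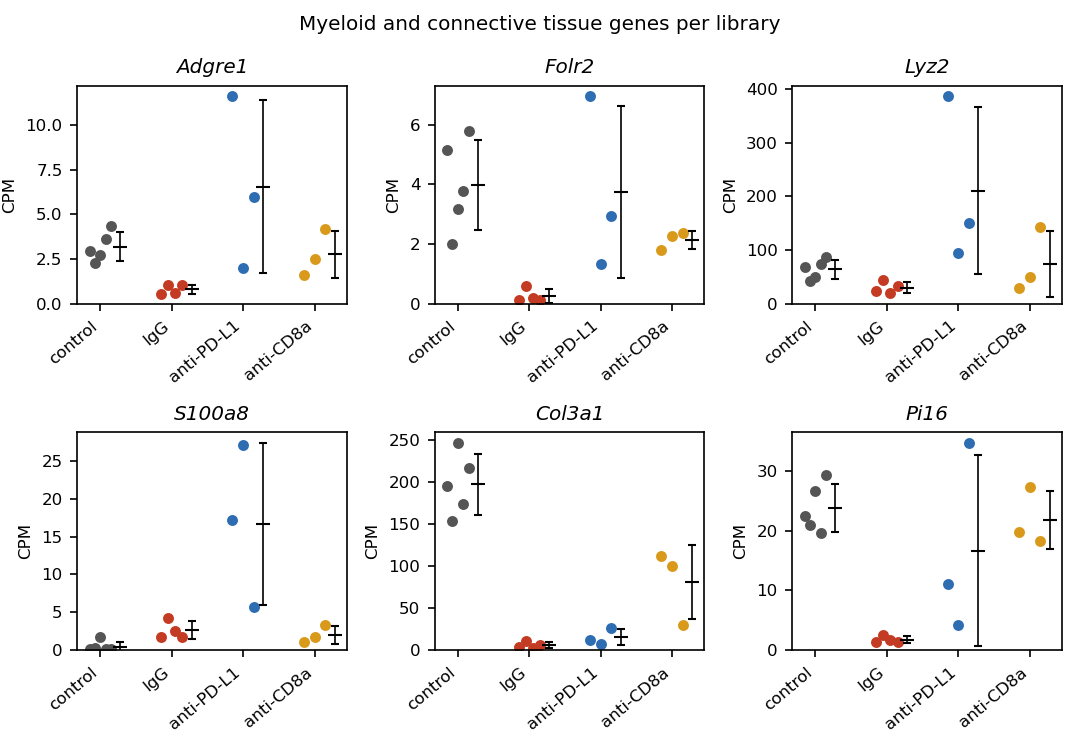
Levels of the macrophage genes Adgre1, Folr2 and Lyz2, the neutrophil gene S100a8 and the matrix genes Col3a1 and Pi16 in CPM on linear axes from 0, with a point for each library and a bar for the mean ± SD of each group. Adgre1 averaged 6.54 CPM in anti-PD-L1 and 0.797 in IgG, and Col3a1 averaged 197 in control and 6.00 in IgG.

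Anti-CD8a against IgG asked what an antibody against cytotoxic T cells did to muscle in tumour-bearing mice. Genes of protein breakdown fell and genes of oxidative phosphorylation and glycolysis rose. Ctsl fell from 381 ± 111 CPM (SD, n = 4) to 88.1 ± 8.62 CPM (SD, n = 3), a log2 fold change of -2.11 ± 0.29 (SE, adjusted p = 5.32e-05). Trim63 fell from 4790 ± 812 to 317 ± 68.5 CPM and Fbxo32 from 4057 ± 646 to 485 ± 181 CPM, log2 fold changes of -3.92 ± 0.57 and -3.06 ± 0.31. Casq1 rose from 259 ± 169 to 1673 ± 477 CPM. In all, 6902 genes changed, 3333 higher and 3569 lower, of which 3512 changed at least 2-fold, and 7664 genes changed without IgG replicate 2 and anti-PD-L1 replicate 2.

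Of the 20 atrophy genes 15 fell (17 adjusted over the list alone; camera adjusted p = 4.51e-07, adjusted p = 0.59 with an estimated correlation), such as Cdkn1a by -4.13 ± 0.65 (SE) and Eif4ebp1 by -3.22 ± 0.29 in log2. All 31 proteasome subunits fell (camera adjusted p = 1.24e-16, adjusted p = 0.534 with an estimated correlation), with Psmd11 at -2.09 ± 0.20. In the lysosome and autophagy list 16 of 26 fell and 2 rose (17 and 2 adjusted over the list alone; camera adjusted p = 3.59e-05, adjusted p = 0.534 with an estimated correlation). Genes of oxidative phosphorylation rose in 37 of 46 cases (39 adjusted over the list alone; camera adjusted p = 2e-10, adjusted p = 0.59 with an estimated correlation), and in 23 without anti-CD8a replicate 2. Cox7a1 rose by 1.54 ± 0.20 and Cyc1 by 1.17 ± 0.15. The mitochondrial share of counts was 7.62 percentage points higher (exact permutation p = 0.0286, two-sided, the smallest this design allows; 0.0572 adjusted over the 6 comparisons). Glycolysis genes rose in 10 of 18 cases and fell in 2 (camera adjusted p = 0.0104, adjusted p = 0.717 with an estimated correlation), with Pgam2 at 1060 ± 119 against 260 ± 96.6 CPM. Fast contractile genes rose in 5 of 16 cases (camera adjusted p = 0.222), with 1 without anti-CD8a replicate 1 and 8 with upper-quartile normalization. Of 12 slow contractile genes 0 passed (camera adjusted p = 0.777), and 2 rose without anti-CD8a replicate 3.

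Matrix genes were higher in anti-CD8a than in IgG: 18 of 24 rose and 1 fell (camera adjusted p = 3.59e-05, adjusted p = 0.59 with an estimated correlation), with Col1a1 at 53.5 ± 27.4 against 3.44 ± 1.89 CPM and Pi16 at 21.8 ± 4.88 against 1.74 ± 0.611 CPM. Tendon cell genes rose in 4 of 8 cases (camera adjusted p = 0.219), Kera by 4.01 ± 0.70 (SE) in log2. Of 9 Schwann cell genes 2 rose (camera adjusted p = 0.428), and 1 of 12 endothelial genes fell (0 adjusted over the list alone, camera adjusted p = 0.777). The macrophage list had 13 of 23 higher and 1 lower (15 and 1 adjusted over the list alone; camera adjusted p = 0.00724, adjusted p = 0.717 with an estimated correlation), and 5 higher and 2 lower without anti-CD8a replicate 3. Folr2 rose from 0.259 ± 0.231 CPM, near the floor, to 2.14 ± 0.305 CPM while Cd68 fell from 21.3 ± 15.1 to 2.25 ± 1.08 CPM. Interferon response genes rose in 17 of 35 cases and fell in 1 (camera adjusted p = 0.00454, adjusted p = 0.681 with an estimated correlation), with Oasl2, an antiviral protein, up by 2.30 ± 0.50 and Cxcl10 down by -3.25 ± 0.79. In the acute phase list 6 of 18 fell (camera adjusted p = 0.0365, adjusted p = 0.717 with an estimated correlation), Il6ra from 147 ± 44.1 to 14.8 ± 7.86 CPM. Camera lost the macrophage list without anti-CD8a replicate 3 (0.0818) and the acute phase list without IgG replicate 2 or anti-CD8a replicate 1 or 2 (0.0525, 0.0723 and 0.116). None of 6 neutrophil genes passed in edgeR, of which Retnlg had the smallest p, at -1.73 ± 0.85 (adjusted p = 0.105; camera adjusted p = 0.771).

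Cd8a, the target of the antibody, had at most 1 count in an IgG or anti-CD8a library, so a difference was not detectable at this depth. Of 4 T cell genes 2 rose, Cd3e and Cd2 (camera adjusted p = 0.424). Cd3e was 8.24-fold higher in raw counts (95% counting interval 2.46 to 43.1), a call lost without IgG replicate 1, 3 or 4 or anti-CD8a replicate 1 or 2, and Cd2 lost its call without anti-CD8a replicate 3. Of 2 B cell genes 1 rose, Ighm, a call lost without IgG replicate 3 or 4 or anti-CD8a replicate 2, and the list's median of -0.58 had the opposite sign to camera (adjusted p = 0.658, higher). Cd274 stood at 1.62 ± 0.780 against 1.68 ± 0.577 CPM (-0.05 ± 0.49, adjusted p = 0.946). The largest rises were in Irx3os, Lrrc38, Nnat, Apln, Nrep, Plcd4, Foxo6os, Fgfbp1, Tmem233 and Aqp4, a water channel of fast fibres that went from 1.13 ± 0.960 to 31.4 ± 9.47 CPM. The largest falls were in Ripor3, Zxda, Neil2, Wdr62, Unc93a2, the B cell attractant Cxcl13, Hoga1, Doc2b, Cdkn1a and Acot1. Wdr62 went from 24.0 ± 11.2 to 1.15 ± 0.104 CPM. Among the 97 named genes that passed, 22 lost the call under at least 1 alternative.

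Anti-PD-L1 against control set the treated tumour-bearing mice against mice without tumour. Atrophy and inflammatory genes were higher, and matrix, oxidative phosphorylation and glycolysis genes lower. Ctsl stood at 281 ± 122 CPM (SD, n = 3) against 80.2 ± 6.59 (SD, n = 5), a log2 fold change of 1.81 ± 0.25 (SE, adjusted p = 0.000132), Trim63 at 3878 ± 2606 against 521 ± 422 CPM and Fbxo32 at 3063 ± 1061 against 465 ± 113 CPM. Chil3, a protein of activated macrophages, rose by 6.99 ± 0.90, Cxcl13 by 5.46 ± 0.67 and the neutrophil genes S100a8 and S100a9 by 5.22 ± 0.69 and 4.69 ± 0.73. In all, 4988 genes changed, 2989 higher and 1999 lower, with 3013 without anti-PD-L1 replicate 2 and 3508 without IgG replicate 2 and anti-PD-L1 replicate 2.

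Higher in anti-PD-L1 than in control were 16 of 20 atrophy genes (18 adjusted over the list alone; camera adjusted p = 2.78e-09), 29 of 31 proteasome subunits (30; camera adjusted p = 6.3e-16) and 17 of 26 lysosome genes (17; camera adjusted p = 1e-06), each with adjusted p = 0.273 with an estimated correlation. Ddit4, an inhibitor of the growth kinase mTOR, rose from 55.6 ± 49.8 to 499 ± 93.8 CPM. Macrophage genes rose in 12 of 23 cases (15 adjusted over the list alone; camera adjusted p = 0.000101, adjusted p = 0.415 with an estimated correlation), and in 6 without anti-PD-L1 replicate 1. Itgam, an integrin of myeloid cells, rose from 2.62 ± 1.60 to 11.4 ± 6.55 CPM. Neutrophil genes rose in 5 of 6 cases (camera adjusted p = 0.00255) and acute phase genes in 11 of 18 (14 adjusted over the list alone; camera adjusted p = 2.11e-05), each with adjusted p = 0.273 with an estimated correlation. Interferon response genes fell in 18 of 35 cases (21 adjusted over the list alone; camera adjusted p = 1.8e-07, adjusted p = 0.273 with an estimated correlation), such as Gbp4 from 7.47 ± 4.61 to 1.47 ± 0.481 CPM. Cd274 fell by a log2 change of -1.72 ± 0.49 (SE, adjusted p = 0.0131), a call lost with voom and sample quality weights and without anti-PD-L1 replicate 2 or 3.

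Matrix genes fell in 14 of 24 cases and rose in 2 (15 and 2 adjusted over the list alone; camera adjusted p = 1.35e-06, adjusted p = 0.273 with an estimated correlation), with Col3a1 at 15.6 ± 10.0 against 197 ± 36.1 CPM. Tendon cell genes fell in 4 of 8 cases (camera adjusted p = 0.00255, adjusted p = 0.273 with an estimated correlation). Schwann cell genes fell in 4 of 9 (camera adjusted p = 0.00426, adjusted p = 0.495 with an estimated correlation), 2 without anti-PD-L1 replicate 1 and 1 without replicate 3. Endothelial genes fell in 2 of 12 cases and rose in 1 (camera adjusted p = 0.0337, adjusted p = 0.596 with an estimated correlation), or 4 and 0 without anti-PD-L1 replicate 2, and camera lost the list without control replicate 5 or anti-PD-L1 replicate 1 (0.0713 and 0.314). Of 46 oxidative phosphorylation genes 24 fell (31 adjusted over the list alone; camera adjusted p = 8.72e-11, adjusted p = 0.291 with an estimated correlation), Cyc1 by -1.03 ± 0.15 (SE). The mitochondrial share was lower by a difference of -9.66 percentage points (exact permutation p = 0.0179, two-sided, the smallest this design allows; 0.0537 adjusted over the 6 comparisons). Glycolysis genes fell in 9 of 18 cases and rose in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.000656, adjusted p = 0.306 with an estimated correlation), and fell in 3 without anti-PD-L1 replicate 1 and 4 without replicate 2. Fast contractile genes fell in 7 of 16 (camera adjusted p = 0.0172, adjusted p = 0.596 with an estimated correlation), in 2 (camera adjusted p = 0.182) and 3 without anti-PD-L1 replicate 1 and 2 and in 4 and 3 without control replicate 1 and 4, and 0 of 12 slow contractile genes passed (camera adjusted p = 0.904). The T cell list had Cd2 higher and Cd3e lower of 4 (camera adjusted p = 0.586), and Cd2 lost its call without anti-PD-L1 replicate 1 or 3 or control replicate 1, 2, 3 or 4. In the B cell list Igkc was higher and Ighm lower, with a median of 0.89 and a camera sign that was negative (adjusted p = 0.672). The Igkc change was -0.21 without anti-PD-L1 replicate 2, and Ighm lost its call without anti-PD-L1 replicate 1 or 2 or control replicate 1, 2 or 4. The largest falls were in Nrep, Kcng4, Irx3os, Apln and Foxo6os, with log2 fold changes of -5.07 to -4.54, and Gnmt, which uses up the methyl donor of the cell, rose by 4.35 ± 0.47. Of the 96 named genes that passed, 31 lost the call under at least 1 alternative.

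Anti-CD8a against control asked how far muscle of tumour-bearing mice given anti-CD8a differed from muscle without tumour. The atrophy genes did not pass: Ctsl stood at 88.1 ± 8.62 CPM (SD, n = 3) against 80.2 ± 6.59 (SD, n = 5), a log2 fold change of 0.14 ± 0.25 (SE, adjusted p = 0.945), Fbxo32 at 485 ± 181 against 465 ± 113 CPM (0.06 ± 0.26) and Trim63 at 317 ± 68.5 against 521 ± 422 CPM (-0.72 ± 0.48). Of all genes 2 passed. Tbc1d4, a regulator of glucose transporter traffic, rose from 28 ± 2.87 to 51.2 ± 1.45 CPM (0.87 ± 0.13, adjusted p = 0.039), and Spon2, a secreted matrix protein, fell from 1.19 ± 0.285 to 0.122 ± 0.0595 CPM (-3.22 ± 0.47, adjusted p = 0.039). The anti-CD8a mean of Spon2 lay below the floor of 0.134 to 0.189 CPM, so the size of its fall is uncertain. Spon2 also fell in IgG against control, by -2.90 ± 0.42.

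No list had a member past the threshold over all genes in edgeR, where 1109 genes had an unadjusted p under 0.05. With the preset correlation camera called 12 lists, while fry called 3. Fry gave the slow contractile list an adjusted p of 0.37 and the atrophy list one of 0.698. The matrix list had a median log2 fold change of -0.74 (10 lower adjusted over the list alone, camera adjusted p = 6.57e-18, adjusted p = 0.104 with an estimated correlation), with Fbn1, fibrillin, at -1.35 ± 0.28 (SE, adjusted p = 0.178). The interferon list had a median of -0.42 (2 lower adjusted over the list alone, camera adjusted p = 4.72e-11, adjusted p = 0.104 with an estimated correlation), with B2m, the light chain of class I antigen presentation, at -0.68 ± 0.13 (adjusted p = 0.107). Slow contractile genes had a median of 1.97 (8 higher adjusted over the list alone, camera adjusted p = 7.32e-09, adjusted p = 0.395 with an estimated correlation), with Casq2 at 1.41 ± 0.41 (adjusted p = 0.361). The fatty acid list had a median of 0.32 (1 higher adjusted over the list alone, camera adjusted p = 0.000956, adjusted p = 0.672 with an estimated correlation), with Acadm at 0.60 ± 0.15 (adjusted p = 0.242). Schwann cell, tendon cell and endothelial lists had medians of -0.77, -0.92 and -0.30 and camera adjusted p values of 3.33e-05, 0.000736 and 0.00131, with adjusted p = 0.428, 0.395 and 0.657 with an estimated correlation. The atrophy list had a median of 0.19 (camera adjusted p = 0.00501, adjusted p = 0.672 with an estimated correlation), the proteasome list one of 0.09 (0.032, and adjusted p = 0.749 with an estimated correlation), the neutrophil list one of 1.5 (3 higher and 1 lower adjusted over the list alone; 0.0247, and adjusted p = 0.428 with an estimated correlation) and the acute phase list one of 0.27 (0.0487, and adjusted p = 0.672 with an estimated correlation). Some of these camera calls hung on single libraries. The proteasome call was lost without control replicate 2, 3 or 5 or anti-CD8a replicate 1 or 2 (up to 0.179), and the acute phase call without control replicate 1, 2, 4 or 5 or anti-CD8a replicate 3 (up to 0.725). The neutrophil call was lost without control replicate 2 or 5 or anti-CD8a replicate 3 (up to 0.454), and the atrophy call without control replicate 5 or anti-CD8a replicate 3 (up to 0.363). The fatty acid and Schwann cell calls were lost without anti-CD8a replicate 2 (0.169 and 0.073) and the endothelial call without replicate 1 (0.114). With the replicate block the atrophy, acute phase and fatty acid lists did not pass (0.318, 0.339 and 0.0704). The lysosome, macrophage, T cell, B cell, fast contractile, glycolysis and oxidative phosphorylation lists gave camera adjusted p values of 0.268, 0.271, 0.366, 0.272, 0.276, 0.268 and 0.971. Camera called the macrophage list without anti-CD8a replicate 3 (1.59e-05) and oxidative phosphorylation without anti-CD8a replicate 2 (0.00023). With the replicate block it called glycolysis and fast contractile genes (0.0199 and 0.0334). For macrophages the median of -0.01 and the mean of 0.01 differed in sign, and for oxidative phosphorylation camera and the median of 0.01 did. The mitochondrial share differed by 0.251 percentage points (exact permutation p = 0.875, two-sided). Cd274 stood at 1.62 ± 0.780 against 3.22 ± 2.02 CPM (-0.99 ± 0.47, adjusted p = 0.642).

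The count of 2 was 64 with DESeq2, 205 with voom and sample quality weights, 56 in a fit of the 2 groups alone, 65 with no filter on low counts, 7 with upper-quartile normalization and 0 with a mean CPM of at least 1 (edgeR, 928 with an unadjusted p under 0.05). It was 0 without control replicate 1, 3, 4 or 5 or anti-CD8a replicate 1 or 2 and 1 without anti-CD8a replicate 3, and both Tbc1d4 and Spon2 lost their calls without each of these.

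Anti-PD-L1 against anti-CD8a compared the antibodies within tumour-bearing mice. The labels give 200 µg per kg for anti-PD-L1 and 200 µg for anti-CD8a, so as written the doses differed greatly, and antibody and dose cannot be separated unless a unit was misprinted. Ctsl stood at 281 ± 122 CPM (SD, n = 3) against 88.1 ± 8.62 (SD, n = 3), higher by 1.67 ± 0.29 in log2 (SE, adjusted p = 0.002), and Trim63 and Fbxo32 were higher by 3.61 ± 0.58 and 2.66 ± 0.31. Cxcl13 was higher by 5.86 ± 0.86 and Chil3 by 5.46 ± 0.96, and Foxo6os, Nrep and Aqp4 were lower by log2 changes of -4.84 ± 0.56, -4.09 ± 0.54 and -3.73 ± 0.50. In all, 2836 genes changed, 1738 higher and 1098 lower, and 1758 without IgG replicate 2 and anti-PD-L1 replicate 2. The count was 1226 without anti-PD-L1 replicate 2, 1252 without anti-CD8a replicate 1 and 1311 without anti-CD8a replicate 2, and a fit of the 2 groups alone called 1712.

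Atrophy genes were higher in anti-PD-L1 in 13 of 20 cases (15 adjusted over the list alone; camera adjusted p = 4.57e-08), proteasome subunits in 29 of 31 (30; 5.16e-17) and lysosome genes in 14 of 26 (15; 9.08e-07), each with adjusted p = 0.364 with an estimated correlation. Without anti-PD-L1 replicate 2 these counts were 5, 19 and 7, without anti-CD8a replicate 1 atrophy and lysosome genes gave 7 and 8, without replicate 2 they gave 8 and 7, and without replicate 3 lysosome genes gave 9, as they did with upper-quartile normalization. Oxidative phosphorylation genes were lower in 22 of 46 cases (23 adjusted over the list alone; camera adjusted p = 1.4e-12, adjusted p = 0.364 with an estimated correlation), with 6 without anti-CD8a replicate 2 and 10 without anti-PD-L1 replicate 2. The mitochondrial share differed by -9.91 percentage points (exact permutation p = 0.1, two-sided, the smallest this design allows). Macrophage genes were higher in 11 of 23 cases (15 adjusted over the list alone; camera adjusted p = 4.53e-06, adjusted p = 0.46 with an estimated correlation), with 2, 3 and 4 without anti-CD8a replicate 1, anti-CD8a replicate 2 and anti-PD-L1 replicate 1. Lyve1, a receptor of resident macrophages and lymph vessels, stood at 29.2 ± 10.6 against 8.21 ± 2.51 CPM. Neutrophil genes were higher in 4 of 6 cases (5 adjusted over the list alone; camera adjusted p = 0.00722, adjusted p = 0.364 with an estimated correlation) and acute phase genes in 8 of 18 (9 adjusted over the list alone; 0.000569, adjusted p = 0.364 with an estimated correlation). Without anti-CD8a replicate 1, anti-CD8a replicate 2 or anti-PD-L1 replicate 2 these counts were 1, 2 and 2 for neutrophils and 4, 4 and 5 for acute phase genes. Interferon response genes were higher in 2 and lower in 2 of 35 cases with TMM (0 and 2 adjusted over the list alone; camera adjusted p = 0.00722, adjusted p = 0.568 with an estimated correlation), 0 and 4 with RLE or without mitochondrial genes, and 0 and 5 with upper-quartile normalization. Matrix genes were lower in 6 and higher in 3 of 24 (8 and 3 adjusted over the list alone; camera adjusted p = 0.0403, adjusted p = 0.784 with an estimated correlation), and lower in 2 without anti-PD-L1 replicate 1 or 2 or anti-CD8a replicate 1 or 2, and in 10 without anti-PD-L1 replicate 3.

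Glycolysis genes were lower in anti-PD-L1 than in anti-CD8a in 3 and higher in 1 of 18 cases (8 and 1 adjusted over the list alone; camera adjusted p = 0.00165, adjusted p = 0.46 with an estimated correlation), and lower in 1 without anti-PD-L1 replicate 2 or anti-CD8a replicate 1, 8 without anti-PD-L1 replicate 3 and 7 with upper-quartile normalization. Fast contractile genes had 1 of 16 lower (camera adjusted p = 0.0403) and slow contractile genes 1 of 12 lower (camera adjusted p = 0.0084), each with adjusted p = 0.784 with an estimated correlation. Without anti-PD-L1 replicate 3, 4 fast contractile genes were lower. Over the runs with 1 library left out, camera passed slow contractile genes in 4 of 6 (up to 0.227), and fast contractile and matrix genes in 3 of 6 (up to 0.521 and 0.225). Casq1, the fast gene, lost its call without anti-PD-L1 replicate 1 or 2 or anti-CD8a replicate 1, and Myh7b, the slow gene, without replicate 2 of either group. Tendon cell genes had 2 of 8 lower, and Schwann and endothelial genes had 0 past the threshold (camera adjusted p = 0.0639, 0.361 and 0.595), though 2 endothelial genes were higher without anti-PD-L1 replicate 1. None of 4 T cell genes passed (camera adjusted p = 0.697), and of 2 B cell genes Igkc passed (median 2.35, camera of negative sign, adjusted p = 0.83), a call lost without anti-PD-L1 replicate 2 or any 1 of the anti-CD8a libraries. Cd274 stood at 0.982 ± 0.430 against 1.62 ± 0.780 CPM (-0.73 ± 0.54, adjusted p = 0.349). Of the 75 named genes that passed, 34 lost the call under at least 1 alternative.

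**Figure D4:**
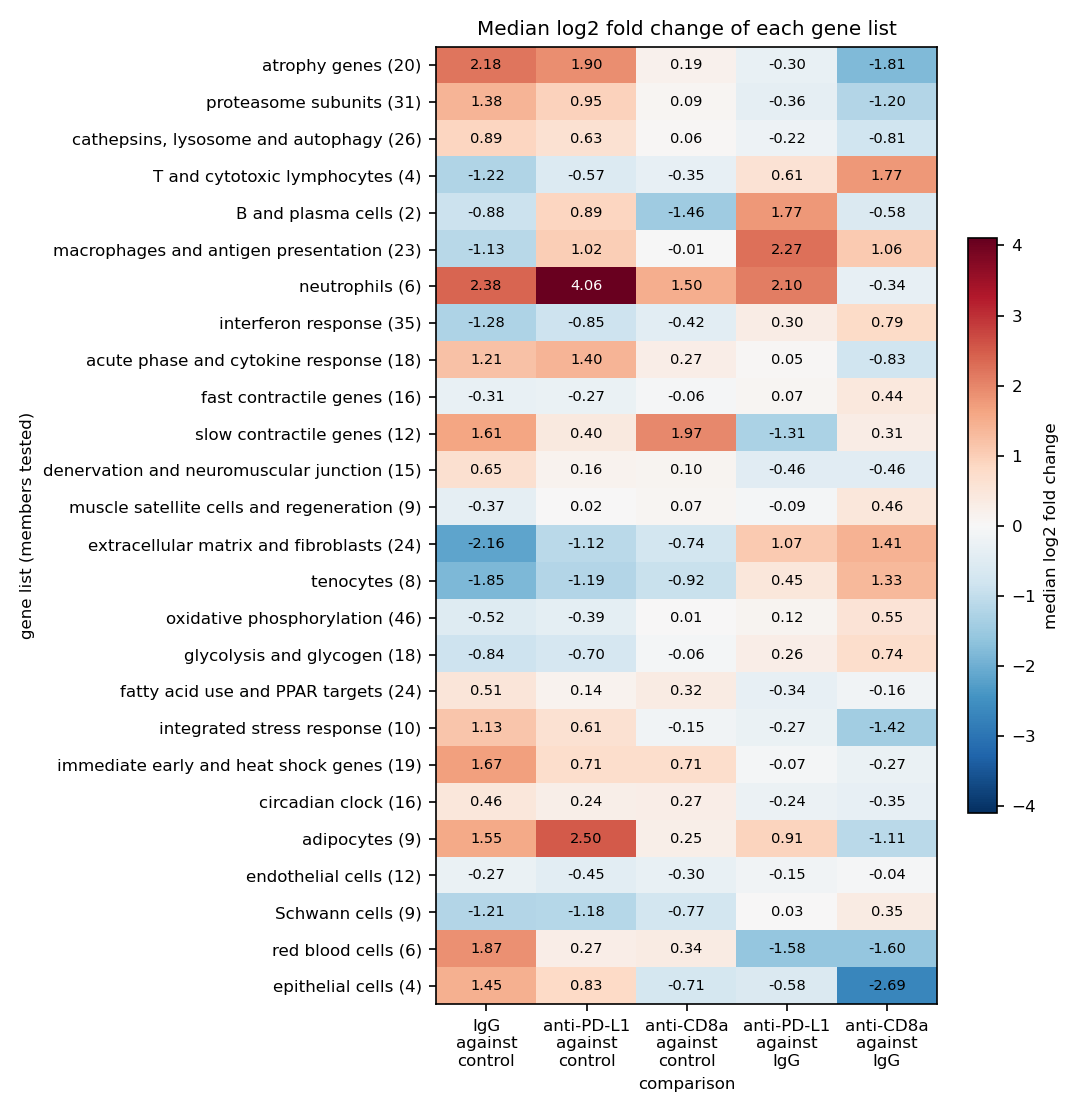
Median log2 fold change of each of the 26 gene lists (rows) in 5 comparisons (columns), with the value printed in each cell. Medians change sign under another scaling for satellite cell, immediate early and Schwann cell genes in anti-PD-L1 against IgG, fatty acid and endothelial genes in anti-CD8a against IgG, satellite cell and fatty acid genes in anti-PD-L1 against control, and oxidative phosphorylation in anti-CD8a against control.

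Comparisons that share a group were set beside each other across genes, which are not independent replicates. Fold changes of anti-PD-L1 and anti-CD8a, each against IgG, correlated at r = 0.665 (covariance 0.454), against 0.443 (0.0593) in simulations of unchanged groups and 0.468 (0.381) with the IgG libraries divided between them. With both antibodies 398 genes were higher and 213 lower, and 5 went opposite ways, where independent lists would share 132 and 55.1. The comparisons share the IgG libraries, so independent lists are no fair reference: with these libraries divided, 0 to 518 genes were higher and 0 to 707 lower in both, and the simulations shared 0. Changes in IgG and anti-PD-L1, each against control, correlated at r = 0.839 (covariance 0.846), against 0.401 (0.0443) in simulations and 0.764 (0.828) with the control libraries divided, with 2646 genes higher and 1835 lower in both and 29 opposite, where independent lists would share 902 and 567. With the control libraries divided, 1259 to 2128 were higher and at most 1410 lower in both. For IgG and anti-CD8a against control, r was 0.383 (covariance 0.197), against 0.401 (0.0447) in simulations and 0.284 (0.169) with the control libraries divided, and for anti-PD-L1 and anti-CD8a against control it was 0.401 (0.155), against 0.379 (0.0454) and 0.279 (0.126). Tbc1d4 was the 1 gene higher and Spon2 the 1 gene lower than control in all 3 tumour-bearing groups. Only these 2 were called in anti-CD8a against control, and both calls were lost there without most single libraries.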

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

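The tests of explanations in this part, and the count of splits for anti-PD-L1 against anti-CD8a, were chosen only after the result was seen.

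Few genes passed in anti-CD8a against control although these mice had been given tumour cells. Over the 4292 genes called at 2-fold or more in IgG against control, the median change in the IgG direction was 1.49 in IgG, 0.923 in anti-PD-L1 and 0.187 in anti-CD8a (mean over its libraries 0.186 ± 0.0209, SE), or 12.5% of the IgG median, with 77% of these genes in the IgG direction. These genes were chosen by their change in the same IgG libraries, which raises the IgG values and biases the 12.5% downwards. Anti-PD-L1 libraries, not used in that choice, still reached 0.659 to 1.25. The value of 0.187 argues against a change as large as in IgG that too few libraries hid, and the shared control libraries bias it upwards. Taken library by library this measure was 0.163 to 0.228 in anti-CD8a, 1.06 to 1.70 in IgG and -0.0917 to 0.117 in control. The 6902 genes changed against IgG do not rest on that choice. With them, 0.228 argues against a tumour that reached the muscle and an antibody without effect, unless an unrecorded difference between the groups gave the gap. Mice that carried no tumour acting on the muscle cannot be told apart, as 0.163 lies near control and no tumour measure was in the data, so that anti-CD8a may have lessened the muscle change stays open as untested.

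Macrophage genes were higher in anti-PD-L1 than in IgG. The mean log2 CPM of the red blood cell genes changed by -1.89 ± 1.4 (SE), 3.96 ± 1.6 below the macrophage genes, which argues against whole blood left in the muscle. Red blood cell genes do not measure white blood cells, and neutrophil genes rose by 1.65 ± 0.426, so white cells from blood are not covered. The macrophage change exceeded the endothelial change by 2.25 ± 0.573, which argues against a lower share of muscle RNA with every other cell type raised alike. Endothelial genes were the only cell type set against them in this way. Matrix genes rose by 0.988 ± 0.355 in mean log2 CPM, while endothelial and Schwann cell genes changed by -0.182 ± 0.292 and 0.183 ± 0.498. A rise shared by some cell types outside the fibres is therefore not argued against. The macrophage change exceeded the adipocyte change by 0.913 ± 1.3, and fat dissected with the muscle cannot be told apart from it at that error. More macrophages, or more of these transcripts in each macrophage, may also account for the macrophage change, and neither was tested. Chance is not excluded either, as 3 of 35 splits of these libraries called as many genes in all as the real one.

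IgG replicate 2 and anti-PD-L1 replicate 2 lay towards the other group, at correlations of 0.963 to 0.966 and 0.963 to 0.964 with their own group, 0.964 to 0.970 and 0.967 to 0.971 with the other group, and 0.977 with each other. An exchange of labels cannot be told apart from libraries that truly differed from their groups, as the mean correlation with the other group was higher by 0.00258 in IgG replicate 2 (SD 0.00262) and by 0.00602 in anti-PD-L1 replicate 2 (SD 0.00152), and 2954 genes passed with these labels exchanged. With IgG replicate 2 alone moved, 2777 passed. Mean list scores went both ways, with both libraries nearer to the other group in 5 of 26 lists, proteasome subunits among them, both nearer to their own in 4, macrophages among them, and 1 of each in 17, while a stricter criterion used first, that each lie nearer to the whole other group than to any library of its own, held for 3 of 5 libraries, spoke against an exchange and was replaced since it took no account of spread. Depth and mitochondrial share are argued against for IgG replicate 2, with both of its 2 values, 16700342 and 20.3%, inside the range of the other libraries. For anti-PD-L1 replicate 2, 0 of 2 were inside. Its total of 22459370, the highest, and its share of 15.5%, the lowest, lay on the side away from IgG. By a rule written after the values were seen this counted against depth and share. It cannot set them aside, as this library was the most extreme of both groups in each. No library was moved to another group, and the groups may differ in how strongly each animal responded, which the labels do not record.

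Other splits of the libraries were counted for each comparison. For IgG against control the real split called 8410 genes, the highest other called 5625, and 1 of 100 splits called as many. For anti-CD8a against IgG (6902 real, 6116 highest other) 1 of 35 splits called as many, and for anti-PD-L1 against control (4988 real, 2 highest other) 1 of 56. In each of these comparisons only the real split reached its count, which argues against chance. Chance is not excluded, as these shares were not adjusted over the comparisons and the libraries may not be separate mice. For anti-CD8a against control 2 of 56 splits called as many as the real 2, and the highest other also called 2, so a count this small says nothing about chance. For anti-PD-L1 against IgG the counts do not argue against chance, as 3 of 35 splits called as many as the real 791 and the highest other called 2954. That split, IgG replicate 2 with anti-PD-L1 replicates 1 and 3, exchanges the labels weighed above, and it called several times the real count, which points to a structure of the samples. Moving IgG replicate 2 alone to the anti-PD-L1 libraries called 2777, so the higher count does not need the exchange of both. For anti-PD-L1 against anti-CD8a the 10 splits of 3 against 3 are too few for a share under 0.05, with 2836 genes in the real split, 1 in the highest other and 1 split with as many.

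In control and IgG, single libraries stood far from their group in 20 of 177 combinations of a gene or list with a group. Each was found because the gap to the next library was large against the range of the group. The rule was meant to flag about 1 in 20 by chance, and that rate was not checked. The anti-PD-L1 and anti-CD8a libraries were not tested for this. IgG replicate 2 had mean log2 CPM of -1.02 in the T cell list (others -1.80 to -1.78), 3.34 in the B cell list (others -0.626 to -0.307) and 3.94 in the matrix list (others 3.28 to 3.31). It had CPM of 0.602 for Folr2 (others 0.122 to 0.189) and 1.44 for Ms4a6c (others 0.504 to 0.621). It had 0.482 for Fgfbp1 (others 0.0611 to 0.126) and 4.57 for Igkc (others 0.122 to 0.248). Its 0.12 for Apln (others 0) lay below the floor of 0.134 to 0.189 CPM. Control replicate 3 had mean log2 CPM of -0.386 in the neutrophil list (others -2.19 to -1.76) and 2.19 in the acute phase list (others 0.756 to 1.10). Its CPM was 1260 for Trim63 (others at most 493), 62.9 for Cdkn1a (others 14.9 to 25.9), 2.07 for Cxcl13 (others 0.162 to 0.446), 1.67 for S100a8 (others 0.0892 to 0.236), 1.61 for S100a9 (others 0 to 0.336) and 1.84 for Igkc (others 0.134 to 0.531). IgG replicate 1 had 3.96 in the endothelial list (others 4.64 to 4.67) and IgG replicate 4 a CPM of 16.8 for Tecrl (others 1.12 to 2.96). Control replicate 5 had a CPM of 1.92 for Clec4a2 (others 0.707 to 1.01) and control replicate 2 one of 0.531 for Neil2 (others 0.108 to 0.223).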

How the results depend on the processing

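Leaving out IgG replicate 2 and anti-PD-L1 replicate 2 together was chosen only after the result was seen, from the outcome itself, so its counts are not independent evidence. The counts of changed genes in IgG against control and anti-CD8a against IgG stayed within 1.5 times under every alternative run except a 2-fold minimum. The cause was not tested where a count moved further, apart from settings that use fewer libraries or genes, or a stricter threshold, by construction. At least a 2-fold change left 4292 genes in IgG against control, 482 in anti-PD-L1 against IgG, 3512 in anti-CD8a against IgG, 2022 in anti-PD-L1 against control, 1 in anti-CD8a against control and 1311 in anti-PD-L1 against anti-CD8a. With the replicate block the counts were 69 in anti-PD-L1 against IgG, 1722 in anti-PD-L1 against anti-CD8a and 0 in anti-CD8a against control (edgeR, 690 with an unadjusted p under 0.05). For anti-CD8a against control, upper-quartile normalization gave 7, no filter on low counts 65, voom with sample quality weights 205, only the 2 groups compared 56, DESeq2 64 and a mean CPM of at least 1 gave 0 (edgeR, 928 with an unadjusted p under 0.05). For anti-PD-L1 against IgG, voom with sample quality weights gave 464, only the 2 groups compared 37 and DESeq2 1756, and for anti-PD-L1 against anti-CD8a only the 2 groups compared gave 1712. Leaving out each replicate in turn gave 7664 to 8670 in IgG against control, 147 to 2712 in anti-PD-L1 against IgG, 5687 to 7339 in anti-CD8a against IgG, 3013 to 4931 in anti-PD-L1 against control, 0 to 2 in anti-CD8a against control and 1226 to 3011 in anti-PD-L1 against anti-CD8a. Without IgG replicate 2 and anti-PD-L1 replicate 2, anti-PD-L1 against IgG gave 4215 (2230 higher, 1985 lower, 782 shared with the 791) and anti-PD-L1 against anti-CD8a 1758. With upper-quartile normalization the median log2 fold change of all genes was -0.271 in IgG against control, 0.120 in anti-PD-L1 against IgG and 0.250 in anti-CD8a against IgG, against -0.0237, 0.0108 and 0.0226 with TMM. It moved the share of changed genes that were higher from 51.5% to 37.0%, from 71.9% to 85.2% and from 48.3% to 64.5% in these comparisons, and from 59.9% to 44.5% in anti-PD-L1 against control and 61.3% to 45.1% in anti-PD-L1 against anti-CD8a. Without both replicates 2 the share in anti-PD-L1 against IgG was 52.9%. Among lists, camera with an estimated correlation called 0 in each of the 6 comparisons, where camera with the preset called 12, 8, 10, 15, 12 and 13 in IgG against control, anti-PD-L1 against IgG, anti-CD8a against IgG, anti-PD-L1 against control, anti-CD8a against control and anti-PD-L1 against anti-CD8a. Fry called 17, 3, 9, 13, 3 and 8. The log2 fold change of Igkc in anti-PD-L1 against control was reversed without anti-PD-L1 replicate 2, at -0.207, and 5.03 without control replicate 3, the ends of its range with each replicate left out. Correlations between comparisons with the shared libraries divided were 0.468, 0.764, 0.284 and 0.279 for anti-PD-L1 with anti-CD8a against IgG, and for IgG with anti-PD-L1, IgG with anti-CD8a and anti-PD-L1 with anti-CD8a against control. Of values of named genes under the alternatives, 1584 of 1637 kept their direction and side of the threshold in IgG against control, 513 of 699 in anti-PD-L1 against IgG and 1204 of 1294 in anti-CD8a against IgG. Depth limits genes near the floor of 0.134 to 0.189 CPM, Cd8a, Aif1, Apln, Irx3os, Folr2 in IgG and Spon2 in anti-CD8a among them.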

Other observations

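The tests of Ctsl against other genes at the end of this part were chosen only after the result was seen.

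Clock genes moved in opposite directions within IgG against control: 7 of 16 rose and 4 fell (camera adjusted p = 0.346). Dbp, an output gene of the clock, fell from 62.3 ± 22.2 CPM (SD, n = 5) to 3.77 ± 1.5 CPM (SD, n = 4), while the repressors Cry2 and Per1 and the activator Arntl rose by 2.96 ± 0.28, 2.26 ± 0.31 and 1.93 ± 0.28 (SE) in log2. In anti-CD8a against IgG 5 clock genes rose and 7 fell (camera adjusted p = 0.608), with Dbp at 87.9 ± 27.9 CPM (SD, n = 3). Anti-PD-L1 against IgG had 1 lower, Clock, at -0.78 ± 0.18, a call lost without IgG replicate 1 or 4 or anti-PD-L1 replicate 1 or 3 (camera adjusted p = 0.243), while 4 were lower and 1 higher without anti-PD-L1 replicate 2, and anti-PD-L1 against control had 4 higher and 3 lower (camera adjusted p = 0.802), or 2 and 1 without anti-PD-L1 replicate 2. The time of day of collection was not stated. Genes of the integrated stress response, a list that holds the transcription factor Atf4 itself, rose in 6 of 10 cases in IgG against control and fell in 1 (camera adjusted p = 0.075). Atf4 went up from 160 ± 14.3 to 545 ± 108 CPM and Ppp1r15a, which ends the stress response, from 23.2 ± 4.14 to 298 ± 157 CPM. In anti-CD8a against IgG 6 fell (camera adjusted p = 0.0365, 0.0904 without IgG replicate 2, and adjusted p = 0.534 with an estimated correlation), Atf4 by -1.63 ± 0.19. In anti-PD-L1 against IgG 1 fell, Atf4, by -0.74 ± 0.18, a call lost without IgG replicate 1, 3 or 4 or anti-PD-L1 replicate 1 or 3 (camera adjusted p = 0.193). In anti-PD-L1 against anti-CD8a 4 rose, Atf4 by 0.89 ± 0.20 (camera adjusted p = 0.0186, adjusted p = 0.364 with an estimated correlation), and 2 without anti-CD8a replicate 1 or anti-PD-L1 replicate 2. Immediate early and heat shock genes rose in 13 of 19 cases in IgG against control and fell in 1 (camera adjusted p = 0.0186, adjusted p = 0.476 with an estimated correlation), with Btg2 up by 3.51 ± 0.34 and Junb by 3.12 ± 0.53. In anti-CD8a against IgG 5 fell and 1 rose (camera adjusted p = 0.658), or 3 and 0 without anti-CD8a replicate 1 and 4 and 3 with upper-quartile normalization. In anti-PD-L1 against control 8 rose (camera adjusted p = 0.00696, adjusted p = 0.273 with an estimated correlation), or 7 with 2 lower without anti-PD-L1 replicate 3. Anti-CD8a against control had 8 higher adjusted over the list alone and 0 over all genes (camera adjusted p = 3.07e-09, adjusted p = 0.0772 with an estimated correlation), with Egr1 at 20.1 ± 1.94 against 5.12 ± 1.93 CPM (1.97 ± 0.46, adjusted p = 0.189).

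Genes of denervation and the neuromuscular junction rose in 9 of 15 cases and fell in 2 in IgG against control (camera adjusted p = 0.316), or 5 and 4 with upper-quartile normalization and 5 and 2 with the replicate block, with Runx1 up from 2.19 ± 1.17 to 26.2 ± 9.28 CPM and Ankrd1 from 6.46 ± 1.12 to 37.1 ± 8.04 CPM. Runx1 fell in anti-PD-L1 against IgG, by -1.44 ± 0.36 (SE), a call lost without IgG replicate 1, 3 or 4 or anti-PD-L1 replicate 1 or 3, as the 1 of 15 members to pass (camera adjusted p = 0.0607). In anti-CD8a against IgG 6 fell and 2 rose, Runx1 by -3.49 ± 0.41 (camera adjusted p = 0.407). Satellite cell genes rose in 2 and fell in 4 of 9 cases in IgG against control (camera adjusted p = 0.746). Myod1, a factor of muscle stem cells, fell from 10.8 ± 1.34 to 3.64 ± 2.03 CPM and Cdh15 rose from 15.1 ± 1.41 to 34.5 ± 14.0 CPM. Their list in anti-PD-L1 against IgG had a median of -0.09 and a mean of 0.22, with 1 member higher (camera adjusted p = 0.753). Fatty acid genes rose in 10 of 24 cases and fell in 2 in IgG against control (camera adjusted p = 0.113), or 5 and 1 without IgG replicate 4 and 6 and 2 with upper-quartile normalization, with Acot1 at 42.7 ± 42.8 against 1.52 ± 0.811 CPM and Acot2 at 86.4 ± 58.8 against 18.2 ± 8.33 CPM. In anti-CD8a against IgG 2 fatty acid genes rose and 4 fell (camera adjusted p = 0.674), or 2 and 2 with upper-quartile normalization or without anti-CD8a replicate 1 or 3. In anti-PD-L1 against control 3 rose and 1 fell (camera adjusted p = 0.691), or 0 and 1 without anti-PD-L1 replicate 2 and 5 and 0 without replicate 3. Adipocyte genes in IgG against control had 1 of 9 higher, Plin4, at 634 ± 23.8 against 220 ± 104 CPM (camera adjusted p = 0.551), and 4 higher without IgG replicate 3. In anti-PD-L1 against control 6 of 9 rose, and 1 without anti-PD-L1 replicate 2 (camera adjusted p = 0.064). With each replicate left out, camera passed this list in 4 of 8 runs (0.00233 to 0.315). All 6 measured red blood cell genes rose in IgG against control (camera adjusted p = 0.17), and 3 without IgG replicate 1, with Alas2 at 23.1 ± 16.4 against 4.35 ± 0.637 CPM. Epithelial genes had 2 of 4 higher in IgG, Krt8 and Krt18, and both calls were lost without IgG replicate 4 (camera adjusted p = 0.586).

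Whether Ctsl follows other genes was tested over the 7 IgG and anti-PD-L1 libraries, in log2 CPM, as a hypothesis with 4 relations. With Fbxo32, Pearson's r was 0.689 (exact permutation p = 0.079, adjusted 0.139) and Spearman's rho 0.893 (exact permutation p = 0.0123, adjusted 0.0492), and r was 0.953 without anti-PD-L1 replicate 3 and IgG replicate 2, the libraries farthest from the median. With Trim63 r was 0.665 (exact permutation p = 0.105, adjusted 0.139), rho 0.714 (0.0881, adjusted 0.117) and r 0.773 without those libraries. A common regulation of Ctsl and these ligases may be present, but r did not pass in either case and 7 libraries are too few to decide. With the macrophage gene Adgre1 r was -0.559 (exact permutation p = 0.183), rho -0.536 (0.236) and r -0.825 without those libraries, which passed in neither direction and decides nothing about macrophages as the source of Ctsl. With the matrix gene Col3a1 r was -0.846 (exact permutation p = 0.0149, adjusted 0.0595), rho -0.75 (0.0663, adjusted 0.117) and r -0.551 without those libraries, so the relation rests partly on them. With each group centred, r over the 7 libraries was 0.592, 0.586, -0.397 and -0.830 for Fbxo32, Trim63, Adgre1 and Col3a1 (exact permutation p within groups 0.326, 0.368, 0.618 and 0.0625, adjusted 0.491, 0.491, 0.618 and 0.25), so no relation passed within groups.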
